A study of Gallus gallus with 6 samples.

How the data were processed

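Brains of chick embryos (Gallus gallus) at stage 29, which the labels place at 6 to 6.5 days of incubation, were sexed genetically and pooled by sex. Each pool held 5 to 8 embryos, and 3 female and 3 male pools were each put on 1 Affymetrix chicken expression array. Total RNA was purified, copied into cDNA from oligo(dT) primers and transcribed into biotin-labelled RNA, per the labels' protocols. An oligo(dT) start favours the 3' end of transcripts, so the signal of a probe set depends on where in the transcript it lies, and levels were compared between pools within a probe set only.

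The deposited values are log2 expression values, 1 per probe set and array, and they were made with RMA from the affy package, per the submitters' processing notes. The versions of both are not given in the sources used here. RMA subtracts background, gives the arrays the same distribution of probe intensities and summarises the probes of a probe set, so it carries no detection call, and a difference shared by most genes would be removed. The array medians lay between 4.84 and 4.87 log2 units, as such scaling gives. The log2 scale was read from the values themselves, which ran from 2.28 to 14.1, and no further scaling was applied.

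The table held 38535 probe sets. The 153 control and reporter probe sets and 689 probe sets for viral and other non-chicken sequences were left out of the tests, and 37693 chicken probe sets were tested without a filter on dim ones. The viral probe sets were used as a picture of background: the 95th percentile of their mean signal was 4.21. The platform annotation named 1 gene for 27166 chicken probe sets, several genes for 177 and none for 10350. Genes were named only from probe sets with 1 gene. Gene identifiers of 26851 probe sets matched the RefSeq annotation of the assembly GRCg7b, which gave chromosome membership and gene order, while 315 with 1 symbol did not match. The array names no genome build, so no coordinates are given. By this annotation 25589 probe sets were autosomal, 1181 lay on the Z, 39 on the W and 10884 had no place.

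Males and females were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, as male minus female, two-sided, with Benjamini-Hochberg adjustment over the 37693 probe sets and a threshold of 0.05 on the adjusted p. Sex was the only term of the model. The standard errors (SE) are those of limma's moderated fit, and SD is the spread over the 3 pools of a sex. These p-values measure the spread between pools, each of which already averages several embryos, and say nothing of the spread between single embryos. An array experiment has no read depth, and the number of arrays limits the precision.

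For tests on groups of genes, each gene was represented by its probe set of highest mean signal. The list tests used camera with a preset correlation of 0.01 between genes, two-sided, and each was repeated with the correlation estimated from the data. All 22 gene lists were written before the data were examined. Of their 661 entries 555 were matched to the array by name, 16 of them through a synonym, so that a gene listed under another name could be missed, and lists were tested over all members and, where at least 5 remained, on autosomal members alone, which left 19 lists. The Z shift used genes at or above the median signal of chicken probe sets, 4.91. For each array the mean deviation of Z genes from their own mean over all arrays, minus the same for autosomal genes, was compared between the sexes by an exact permutation test, two-sided. With 3 pools against 3 the smallest p this test can give is 0.1. The Z lists were compared with other Z genes by camera. For neighbouring genes, medians over 15 Z genes in order were set against 10000 shuffles of that order, a test chosen after the data had been seen.

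The named genes followed a rule fixed before the data were examined. Among probe sets with 1 gene and an adjusted p under 0.05, with 1 probe set per gene (the smallest p), these were the 10 largest differences higher in males, the 10 higher in females and the 10 largest on autosomes. Every W gene on the array, and every gene of the MHM region, steroid synthesis and hormone receptor lists, could be named. From each other list these were the members past the threshold, at most 4, or where none passed, the 2 of smallest p. Other names are marked as chosen after their values were seen.

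The procedure was tested on simulated data made from the means and residual spread of the 37693 probe sets, with 200 probe sets changed in the comparison of males and females. It recovered 26.0% of 50 probe sets changed by 0.5 log2 units, 64.0% of 50 changed by 1, 96.0% of 50 changed by 2 and all 50 changed by 4, with 7 false calls and none of the wrong sign. In simulated lists over 13008 genes a Z shift of 0.4 was recovered and 0 of 19 unshifted lists passed. The simulated genes varied independently of each other. The simulation therefore cannot show how often lists pass falsely when genes are correlated. The residual spreads were also shuffled among probe sets, so any link between signal and spread was lost. The recovery and the false calls hold for that setting.

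The alternatives were quantile normalization again, centring on the autosomal median, filters on dim probe sets, the replicate number as a block, eBayes with trend and robust settings, array weights, a threshold of 0.01, the mean of all probe sets of a gene, an estimated correlation and leaving out each pool. A removal of the trend with gene span, a filter at the viral background and the removal of both pools numbered 3 were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).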

Results

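Expression was measured on 6 arrays, 1 for each of 3 pools of female and 3 pools of male chick brain at stage 29, to ask which genes differ in activity between the sexes in the embryonic brain. In birds the male carries a pair of Z chromosomes and the female a Z and a W, so the comparison covers W genes that males lack, Z genes that males carry in an extra copy, and autosomal genes that both sexes carry alike. Over all probe sets Pearson's r between arrays of the same sex was 0.991 to 0.995 (6 pairs) and between the sexes 0.988 to 0.992 (9 pairs). In all, 209 of 37693 chicken probe sets differed between the sexes at an adjusted p under 0.05 (limma, Benjamini-Hochberg, n = 3 pools per sex), 167 of them higher in males and 42 higher in females. Of these, 136 lay on the Z, 14 on the W, 11 on autosomes, and 48 had no place in the annotation. At an unadjusted p under 0.05 there were 3931, of which 1983 were higher in males. The count rested on every pool: it was 113 without female pool 2, 129 without female pool 3 and 130 without male pool 1.

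W-linked genes gave the largest differences and serve as a check on the sexing. HINTW, a W-linked relative of a histidine triad protein, had a signal of 13.20 ± 0.11 (SD, n = 3) in female pools and 5.25 ± 0.67 in male pools, a male minus female difference of -7.95 (SE 0.29). UBE2R2L, named for an E2 ubiquitin-conjugating enzyme, differed by -5.86 (SE 0.14), HNRNPKL, named for an RNA-binding protein, by -4.73 (SE 0.19) and SPIN1L, named for the chromatin reader spindlin, by -4.57 (SE 0.17). The uncharacterised W genes LOC430910 and LOC107049459 differed by -5.65 and -4.22. LOC427010 (-1.71), LOC431003 (-1.68) and UBAP2L2 (-1.56) also passed. The male means of UBE2R2L, HNRNPKL and SPIN1L (3.24, 2.71 and 2.81) lay at background.

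Of 17 W genes with 39 probe sets, 9 genes had at least 1 probe set that passed, 14 probe sets in all, and each of the 14 was higher in females. The male means of 10 of the 14 lay under 4.21, the 95th percentile of the viral probe sets, so that for these the male value stood at background, the size of the difference is limited by it, and the sizes do not rank the genes. Of the fixed list of W-linked genes 4 were matched by symbol or synonym, which left out UBE2R2L, HNRNPKL and NEDD4L. Of the 4 matched genes 3 passed over all genes and 4 adjusted over the list alone, and the list was lower in males (adjusted p = 1.23e-12, camera with Benjamini-Hochberg, and adjusted p = 0.0296 with an estimated correlation). The member that passed over the list alone only was LOC374195, the W copy of the chromatin remodeller CHD1, at -2.25 (SE 0.45, limma adjusted p = 0.123). In 2 of the 17 genes no probe set was lower in males. One is NEDD4L, a ubiquitin ligase that the annotation places on the W, whose 5 probe sets differed by 0.39 to 0.55 in the other direction, with limma adjusted p of 0.0572 to 0.483. Their male means of 5.85 to 8.89, in a sex without a W, cannot come from a W copy. These probe sets thus do not measure a W copy alone, and may not measure one at all. The same holds for MBD2, also placed on the W, with means of 9.31 in female and 9.16 in male pools. It holds as well for a probe set of LOC425347, with means of 6.46 in female and 6.64 in male pools.

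**Figure D1:**
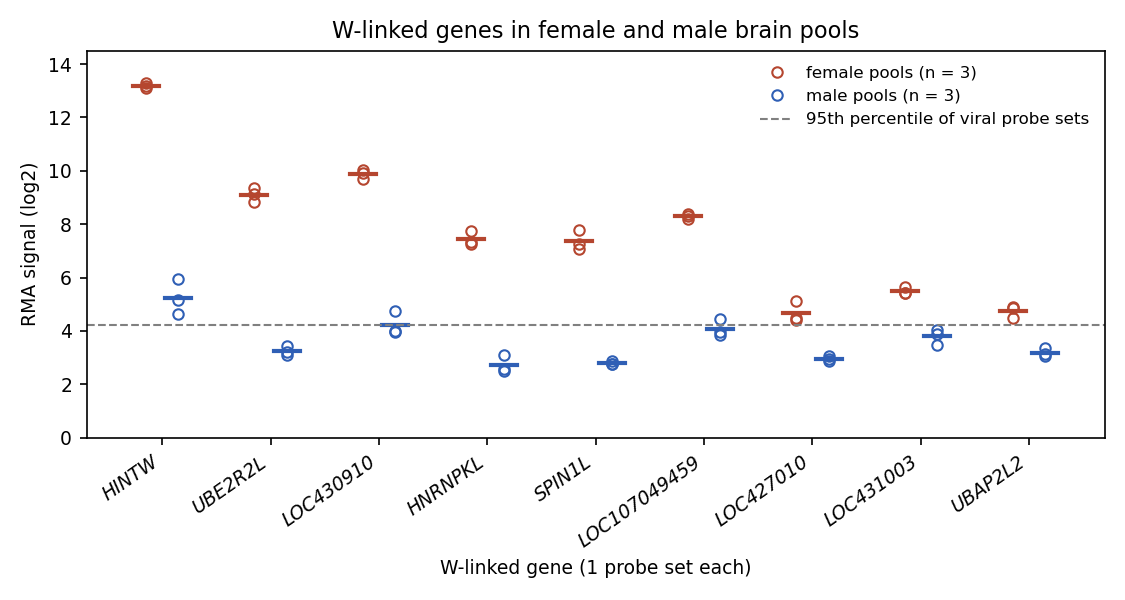
RMA signal (log2) of the 9 W genes that passed, 1 probe set each, in each of 3 female and 3 male pools (circles) with the group means (bars); the dashed line marks 4.21, the 95th percentile of viral probe sets. The female circles lie above the male circles for every gene shown, with HINTW furthest apart at means of 13.20 and 5.25.

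Z-linked genes were higher in males. All 136 Z probe sets that passed, of 1181 tested and belonging to 110 genes, were higher in males, by 0.47 to 1.43 log2 units with a median of 0.88. Among probe sets that passed and had 1 named gene, the 10 genes with the largest differences higher in males were all Z-linked. AK6, an adenylate kinase family member, was higher by 1.43 (SE 0.13, 2.70-fold), GRHPR, an enzyme of glyoxylate metabolism, by 1.28 (SE 0.14), and CKS2, a partner of cyclin-dependent kinases, by 1.24 (SE 0.09). The mitochondrial ribosomal proteins MRPL17 and MRPS30 were higher by 1.21 (SE 0.08) and 1.10 (SE 0.13). FSD1L (1.19), the checkpoint gene RAD1 (1.17), TTC33 (1.13), the hydrolase NUDT2 (1.11) and HAUS1 (1.09), a part of the augmin complex of the spindle, completed the set, with adjusted p between 0.00141 and 0.0173 for the 10 genes (limma, Benjamini-Hochberg). AK6 and FSD1L passed with 1 of 3 and 1 of 2 probe sets, while MRPL17 passed with all 3.

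The chromosome as a whole was shifted by less than a doubling. Over 377 Z genes at or above the median signal, the median male minus female difference was 0.36 (1.28-fold, quartiles 0.09 and 0.74), against 0.01 over 8688 autosomal genes, whose SD was 0.19. The difference was above 0 for 323 of the 377 (85.7%). It was at least 0.8 for 77 genes and at least 1 for 26, while 131 genes lay under 0.2. Per array, the mean deviation of Z genes relative to autosomal genes was 0.21 ± 0.06 (SD, n = 3) in male pools and -0.21 ± 0.03 in female pools, a difference of 0.43 (1.35-fold). Every male pool lay above every female pool, and the exact permutation test, two-sided, gave p = 0.1, the smallest that 3 pools against 3 allow. Against all other genes the Z set passed in camera at p = 4.45e-48, and at p = 0.00119 with an estimated correlation. The median difference was 0.17 in the dimmest 126 genes, 0.44 in the middle 125 and 0.51 in the brightest 126, and the shift per array was 0.30 without a filter on signal.

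**Figure D2:**
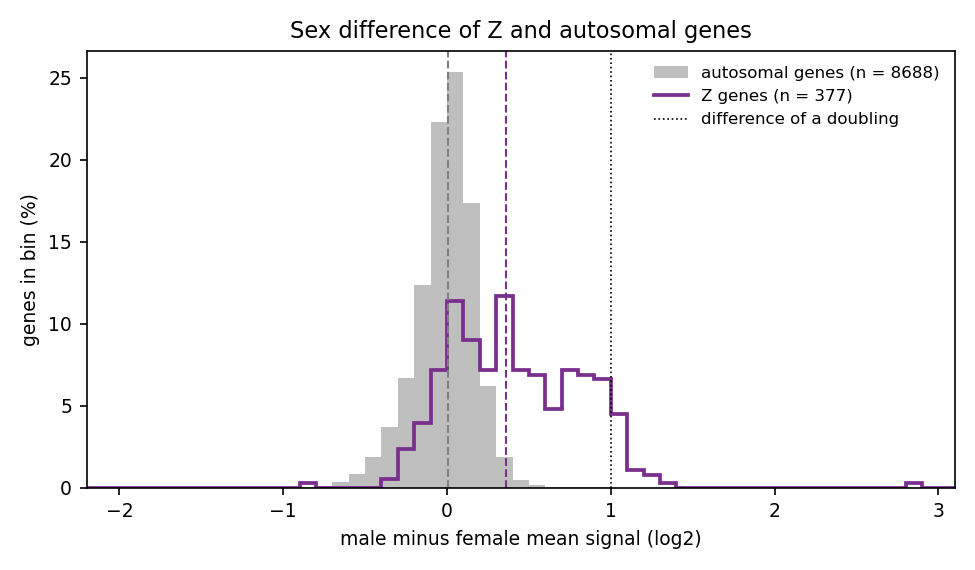
Share of genes (%) by male minus female mean signal (log2, bins of 0.1) for 377 Z genes (line) and 8688 autosomal genes (grey), all at or above the median signal, with dashed lines at the medians of 0.36 and 0.01 and a dotted line at a doubling. Of the 377 Z genes 323 lie above 0 and 26 reach the doubling, with 1 gene far out in the bin that starts at 2.8.

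Genes around DMRT1, the Z-linked testis gene beside the male hypermethylated (MHM) region, did not share the male excess. The 22 members of the MHM region list on the array had a mean difference of 0.00, against 0.30 for other Z genes (camera among Z genes, adjusted p = 0.000109 over the 2 Z lists). The call was lost with an estimated correlation (adjusted p = 0.0521). Differences were below 0 for 14 members and above 0 for 8. RCL1, an RNA-processing gene, passed over all genes at 0.52 (SE 0.08, limma adjusted p = 0.0462), and adjusted over the list alone CBWD1 passed as well, at 0.59 (SE 0.11). DMRT1 itself gave -0.04 (SE 0.14) at a mean signal of 4.19, under the viral 95th percentile, DMRT3 0.10 (SE 0.08), the lipoprotein receptor gene VLDLR 0.14 (SE 0.10), the chromatin remodeller SMARCA2 -0.26 (SE 0.13) and the transcription factor RFX3 -0.35 (SE 0.27). None of these 5 passed.

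Gene order, read from the same values and so not separate evidence, pointed to a stretch beside DMRT3 that does not hold it. In the assembly GRCg7b, the 15 neighbouring Z genes with the lowest median ran from SMARCA2, next to DMRT3, to the transcription factor gene NFIB. Their median was -0.06, and 21 of 10000 shuffles of gene order gave a window as low anywhere on the Z. The shuffles were not matched for gene span or signal, and the male excess was smaller in long and in dim Z genes. They therefore cannot tell a local effect from a run of long or dim neighbours. The next lowest window that did not overlap ran from the glutamate transporter SLC1A3 to SELENOP1 (median -0.00), and the highest ran from MTAP to POLR1E (median 0.80). These window genes were singled out after their values were seen.

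**Figure D3:**
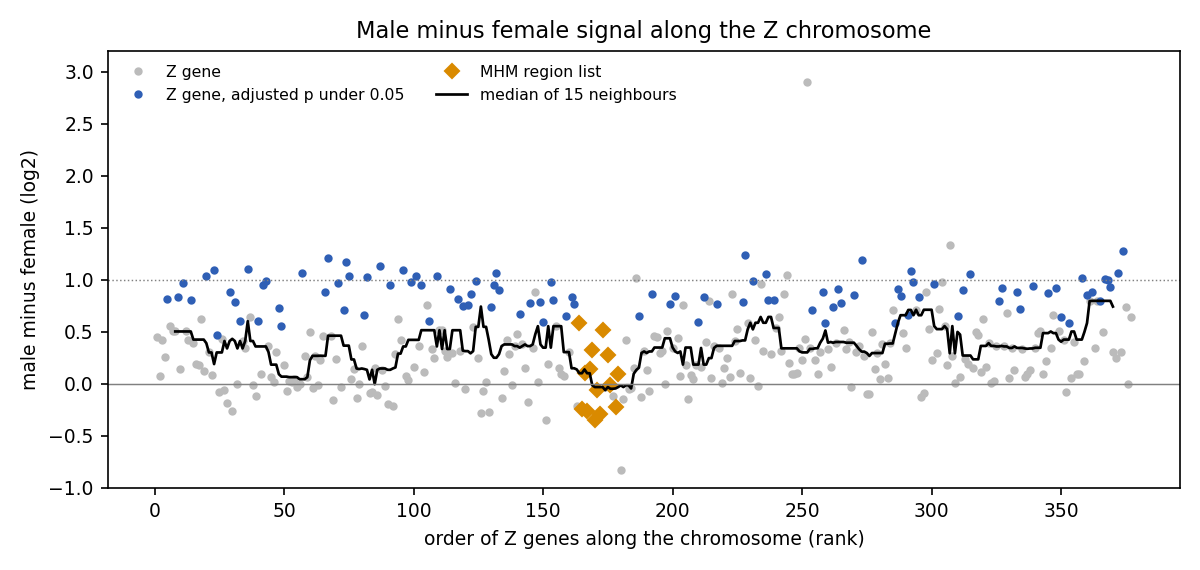
Male minus female signal (log2) of the 377 Z genes at or above the median signal, by rank along the Z in GRCg7b, as points, with the MHM region list as diamonds (RCL1 among them passed) and the running median of 15 neighbours as a line; the dotted line marks a doubling. The running median falls to -0.06 around ranks 167 to 181 and reaches 0.80 at its highest.

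Z genes that keep a partner copy on the W were also higher in males. Of 19 on the array 17 had a positive difference. Over all genes 5 rose: TXNL1, a thioredoxin-like protein, by 0.82 (SE 0.07), HINT2, which the annotation lists with the synonym HINTZ, by 0.80 (SE 0.07), SPIN1, a chromatin reader, by 0.78 (SE 0.10), the ubiquitin-conjugating enzyme UBE2R2 by 0.60 (SE 0.08) and the ATP synthase subunit ATP5F1AZ by 0.47 (SE 0.07). Adjusted over the list alone 16 passed, 15 of them higher in males. The exception was ZSWIM6, named after its value was seen, at -0.37 (SE 0.08). The list as a whole was higher in males against all other genes (adjusted p = 9.25e-15, camera with Benjamini-Hochberg, and adjusted p = 0.0296 with an estimated correlation). Its mean of 0.43 lay above the 0.29 of other Z genes (camera among Z genes, adjusted p = 0.00771), a call that was lost with an estimated correlation (adjusted p = 0.0716). Restricted to probe sets above the viral background, a setting chosen after the data had been seen, the gap was 0.0854 and no longer passed.

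On the autosomes 11 of 25589 probe sets passed, 10 lower and 1 higher in males, in 10 genes. GFRA1, the receptor of the growth factor GDNF, had the largest difference, -1.29 (SE 0.20, n = 3, limma adjusted p = 0.0441), with 5.99 ± 0.38 (SD) in female and 4.69 ± 0.25 in male pools. Also lower in males were the translation initiation factor EIF4G3 (-0.78), the transcriptional coregulator ZMIZ1 (-0.69), APAF1 of the apoptosome (-0.65 in a probe set whose means of 4.12 and 3.47 lie under the viral 95th percentile, with -0.16 and 0.01 in its 2 brighter probe sets), PQLC3 (-0.64), LOC426626 (-0.64), the histone methyltransferase family member KMT2E (-0.62), the microtubule-binding protein CLASP1 (-0.57) and NES (-0.55), which encodes nestin, an intermediate filament of neural progenitors. LOC422442 was higher in males by 0.59. The adjusted p of the 10 genes ran from 0.0112 to 0.0450 (limma, Benjamini-Hochberg). GFRA1 and NES have 1 probe set each. In the other 8 genes some probe sets did not pass, and for EIF4G3, APAF1 and CLASP1 1 other probe set had the opposite sign. That probe set gave 0.01 for APAF1. For EIF4G3 and CLASP1 it gave 0.12 each, at signals under the viral 95th percentile. A second probe set of EIF4G3 passed at -0.68.

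This autosomal set was fragile. At an adjusted p under 0.01 the count was 0, with 2468 autosomal probe sets at an unadjusted p under 0.05 (limma). It was 2 without female pool 2, 3 without female pool 3, 3 without male pool 1 and 5 without male pool 3. Of the probe sets that passed, 2 were higher in males without each of these first 3 pools, and 1 of the 5 without male pool 3. The count was 13 without female pool 1 and 15 without male pool 2, so not every removal lowered it. With eBayes set to trend and robust 24 passed, all 11 among them, and with array weights the same 11 passed. With the replicate number as a block 32 passed, with 6 of the 11 among them. Without both pools numbered 3, a setting chosen after the data had been seen, 5 passed and 0 of the 11 were kept.

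Among the fixed lists, tested on autosomal members, genes of postmitotic neurons were lower in males as a group, with a mean difference of -0.21 over 23 genes, 20 of them below 0 (adjusted p = 1.62e-05 over 19 lists, camera with Benjamini-Hochberg, and adjusted p = 0.272 with an estimated correlation). No member passed over all genes, and 3 passed adjusted over the list alone: the synaptic vesicle calcium sensor SYT1 at -0.41 (SE 0.09), the kinesin KIF5C at -0.36 (SE 0.08) and the transcription factor NHLH1 at -0.34 (SE 0.09). Neural progenitor genes were also lower, with a mean of -0.14 over 25 genes (camera adjusted p = 0.00190, and adjusted p = 0.471 with an estimated correlation). NES fell over all genes, and adjusted over the list alone the stem cell factor SOX2, at -0.29 (SE 0.07), and the receptor NOTCH1, at -0.48 (SE 0.12), passed as well. NHLH1, SOX2 and NOTCH1 were named after their values were seen. Without female pool 3 the progenitor list had an adjusted p of 0.0720 (camera). In that pool 7 of 13 HOX genes, patterning genes of hindbrain and spinal cord, differed from the mean of the other pools by -1.06 to -3.67, with HOXA3, named after its values were seen, at 3.25, while the other 6 lay between -0.10 and 0.13 of it.

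Chromatin regulators were lower in males, with a mean of -0.15 over 24 autosomal genes (camera adjusted p = 0.00563, and adjusted p = 0.272 with an estimated correlation). None passed over all genes, and SMARCA4, an ATPase of chromatin remodelling, passed adjusted over the list alone at -0.45 (SE 0.08), while the remodeller CHD7 gave -0.35 (SE 0.10). Genes of oxidative phosphorylation were higher in males. Their 41 autosomal members had a mean of 0.12 (camera adjusted p = 9.04e-05, and adjusted p = 0.454 with an estimated correlation), and none of these passed singly. The 4 members that rose are Z-linked: the complex I subunit NDUFS4 by 0.95 (SE 0.10) and its assembly factor NDUFAF2 by 0.91 (SE 0.13), the cytochrome oxidase subunit COX7C by 0.83 (SE 0.08), and ATP5F1AZ. The same 4 passed adjusted over the list alone, and 1 other probe set of NDUFS4 had the opposite sign. Muscle genes, listed as a check on other tissues, were higher in males by a mean of 0.10 over 23 genes (camera adjusted p = 0.00563, and adjusted p = 0.272 with an estimated correlation). Only 5 of the 23 reached the median signal, no member passed in either adjustment, and among genes above it the adjusted p was 0.298. MYL1, a myosin light chain, gave 0.38 (SE 0.09) at a signal under the viral 95th percentile and the troponin TNNI2 0.33 (SE 0.09). Beside all of these lists, the male minus female difference fell with the genomic span of a gene over 8688 autosomal genes (Spearman's rho = -0.38, across genes, which are not independent replicates). The median span was 67.6 kb for the neuron list, 23.95 kb for chromatin regulators, 7.71 kb for progenitors, 5.47 kb for muscle and 3.70 kb for oxidative phosphorylation.

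Enzymes of sex steroid synthesis did not pass as a group (21 genes, mean 0.09, camera adjusted p = 0.232, and 18 autosomal genes, mean 0.02, camera adjusted p = 0.764). Of the 21 genes 13 reached the median signal. HSD17B4, a Z-linked enzyme of peroxisomes that also oxidises estradiol, was the only member that rose, by 0.87 (SE 0.09, limma adjusted p = 0.00537), in both adjustments. The Z-linked HSD17B3 gave 0.32 (SE 0.09) and the steroid sulfatase STS -0.33 (SE 0.10), and neither passed. Aromatase, CYP19A1, gave 0.04 (SE 0.12) with means of 3.13 in female and 3.17 in male pools, under the viral 95th percentile. CYP11A1 gave 0.21 (SE 0.11) and CYP17A1 0.06 (SE 0.07). Hormone receptors did not pass as a group (21 genes, mean -0.03, camera adjusted p = 0.566), and only 10 of the 21 reached the median signal. The estrogen receptors ESR1 and ESR2 gave 0.03 (SE 0.08) and -0.04 (SE 0.09), and the thyroid hormone receptor THRA 0.21 (SE 0.07). None passed over all genes, and the mineralocorticoid receptor NR3C2 alone passed adjusted over the list alone, at -0.42 (SE 0.09) and a signal below the viral 95th percentile. Genes of gonadal sex determination did not pass as a group (20 genes, mean -0.01, camera adjusted p = 0.526), and no member passed in either adjustment: SOX8 gave -0.25 (SE 0.08) and the Z-linked FST 0.36 (SE 0.12).

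The remaining lists did not pass on autosomal members (camera adjusted p = 0.0845 to 0.896), and no member passed over all genes by its brightest probe set. For brain regions (31 genes, adjusted p = 0.0929) GATA3 gave -0.44 (SE 0.11) and the forebrain gene DLX5 -0.45 (SE 0.12). For stress and early response (24 genes, adjusted p = 0.0845) EGR1 gave -0.42 (SE 0.11) at a signal under the viral 95th percentile, and the Z-linked chaperone gene DNAJA1, at 0.34 (SE 0.07), passed adjusted over the list alone, while its other probe set passed over all genes. The ribosomal protein list (58 genes, mean 0.03, adjusted p = 0.130) had 1 member that passed adjusted over the list alone, the Z-linked RPL17 at 0.42 (SE 0.07). Among cell cycle genes (25 genes, adjusted p = 0.558) TOP2A gave -0.40 (SE 0.14) and CCNB1 0.20 (SE 0.08), and among transmitter genes (31 genes, adjusted p = 0.250) DDC gave 0.29 (SE 0.08). ACHE, a member of the transmitter list without a place in the annotation, gave -0.69 (SE 0.24). In the glia list (12 genes, adjusted p = 0.302) NFIA, a factor of gliogenesis, passed adjusted over the list alone at -0.69 (SE 0.12, limma adjusted p = 0.0786 over all genes). Markers of other tissues were vascular cells (20 genes, adjusted p = 0.645), macrophages and microglia (18 genes, adjusted p = 0.459), blood cells (13 genes, adjusted p = 0.891), mesenchyme and meninges (27 genes, adjusted p = 0.896) and eye, ear and pigment (20 genes, adjusted p = 0.302). The signs of mean, median and test differed for cell cycle genes (mean -0.01, median 0.04, test higher in males), blood cells (mean 0.07, median -0.02, test higher in females) and mesenchyme (mean -0.05, median 0.03, test higher in females). The embryonic globin gene HBZ gave 0.94 (SE 0.25) with a limma adjusted p of 0.251 and passed in neither adjustment. The fibronectin gene FN1 gave -0.78 (SE 0.17), and VSX1, a retinal factor, 0.51 (SE 0.10); each passed adjusted over its list alone.

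Probe sets without a place in the annotation gave 48 calls among 10884. Of these 30 were higher in males, with a median of 0.76, a size near that of the Z-linked calls, and 18 were higher in females, with a median of -0.98. The male minus female difference was below -2 for 7 of the 18. IPO11, a nuclear import receptor named here after its values were seen, was the only named gene among the 48, with 3 probe sets at 0.58, 0.66 and 0.80.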

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

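Of the tests in this part, those of actin probe sets, of bright genes around DMRT1 and of HOX genes in female pool 3 were chosen only after the result was seen.

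Signal in probe sets that no comparison used drew attention: 8 of 689 viral and other non-chicken probe sets reached the median of chicken probe sets, 4.91. Their mean signals were 7.762, 6.382, 6.002, 5.728, 5.617, 5.585, 5.02 and 4.98. The brightest read 4.08 in female pool 3 and 3.72 in male pool 2 and 9.44 to 9.92 in the other pools. With limma 0 of 689 differed between the sexes, with 63 at an unadjusted p under 0.05.

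Z genes around DMRT1 had a lower male excess than other Z genes. Random Z lists matched for gene span and signal had a median of 0.18 against -0.04 for the list, and the share of draws as low was 1e-04, the smallest that 10000 draws can give, which argues against span and dimness as the whole cause. The bright members alone lay at 0.04 against 0.37 for other bright Z genes, a difference of -0.32. These groups were not matched for signal. Among all bright Z genes the median rose from 0.17 in the dimmest 126 to 0.51 in the brightest 126. The comparison of bright genes therefore cannot decide on compression by weak signal. The local activity of the MHM region in females is a candidate explanation that was not tested.

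In autosomal genes the male minus female difference fell with gene span. The slope on log10 span, male minus female, was -0.12, with every male pool below 0 and every female pool above, so that sex of the pools may account for it, though a handling difference that followed sex would look alike. The actin 5' minus 3' difference was -0.0852, male minus female, within the spread between pools, and the GAPDH one went the other way (0.37 in female and 0.40 in male pools), so RNA integrity or labelling length cannot be told apart from sex here. Among the 5363 genes at or above the upper quartile signal of chicken probe sets, 6.79, rho was -0.42. This argues against dim probe sets as the cause. With the trend removed 4 of 4 lists (neurons, progenitors, chromatin and oxidative phosphorylation) still passed at the preset correlation, which argues against the trend with gene span as the whole cause, but the mean for oxidative phosphorylation, relative to other autosomal genes, went from 0.13 to 0.09, and with an estimated correlation 0 autosomal lists passed even before the removal (adjusted p = 0.272, 0.471, 0.272 and 0.454 for the 4, camera with Benjamini-Hochberg).

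In female pool 3, 9 of 13 HOX genes with signal were at their lowest: HOXA3 read 3.25 there and 6.47 to 7.20 elsewhere, and HOXB3 3.75 against 7.19 to 7.62. In 7 of the 13 the difference from the mean of the other pools was -1.06 to -3.67, while HOXB2, a hindbrain gene, and HOXA11 were lowest by little and the other 4 were not lowest. Of 3506 other autosomal genes of the same signal as these 7, 7 genes (0.1997%) were lower by more than 1 in that pool. The fall was thus not shared by genes of that signal. RMA gives the arrays the same distribution, so a lower signal of the array as a whole could not be tested this way. Less hindbrain tissue in that pool may account for the 7 genes. HOXB2 read 4.98 to 5.13 over all pools. It hardly varied in any pool, so it cannot count for or against less hindbrain tissue. No biological explanation by sex was tested, since the pattern lies in 1 pool.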

How the results depend on the processing

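The removal of the span trend, the filter at the viral background and the removal of both pools numbered 3 were chosen after seeing the data, and the cause of the changes below was not tested unless named. No direction reversed among 38 named genes that passed: over 563 gene settings 446 passed again and 117 did not. The count of probe sets was 108 at an adjusted p under 0.01 (88 higher in males and 20 in females) and 113 to 161 without single pools. Without both pools numbered 3 (fewer samples) it was 52, with 29 higher in males and 23 in females. The autosomal count was 32 with the replicate number as a block (6 of the 11 shared) and 24 with eBayes trend and robust (11 shared). It was 10 with the span trend removed (9 shared) and 5 without both pools numbered 3 (0 shared). At an adjusted p under 0.01 it was 0, and without single pools it was 2 to 15. The labels do not say that a number marks a shared day. Of the lists 2 passed with an estimated correlation and 6 to 8 without single pools; on autosomal members these were 0 and 5 to 6. The Z genes with a W copy differed from other Z genes by 0.14 with an estimated correlation and 0.0854 above the viral background, where neither passed, and by 0.12 to 0.16 without single pools. The MHM difference was -0.32 to -0.28, the Z shift 0.40 to 0.46 and the W count 13 to 18 without single pools. Brain regions and stress genes passed under some alternatives only, with lowest adjusted p of 0.0116 and 0.00615. Signal over background limits the W and muscle values.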

Other observations

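The splits for the counts of probe sets and lists and for the Z shift were tests chosen only after the result was seen, and the genes of the next paragraph were chosen after their values were seen.

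Some probe sets were low in some pools and bright in others whatever the sex, and the cause was not tested. Of 20 probe sets with a gap of at least 3 log2 units between arrays, 11 followed sex and 9 did not. SRI, which encodes the calcium-binding protein sorcin, read 2.92 in female pool 2 and 3.05 in male pool 1 and 8.58 to 8.82 in the other pools. FAM174A, a Z gene, read 3.13 in female pool 2 and 8.60 to 9.82 elsewhere. LOC770705 read 3.81 in female pool 3 and 3.90 in male pool 2 and 9.28 to 9.78 elsewhere, the same pools in which the brightest viral probe set was low. RDM1, a recombination gene, read 3.73 in male pool 1 and 7.14 to 8.52 elsewhere. In female pool 3 the 12 rostral patterning genes, OTX2 and EMX2 among them, had a median deviation of 0.24, against -1.06 for 13 HOX genes, and HOXA6 was low in male pool 3 (4.40) as well as in female pool 3 (4.19).

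The male excess of Z genes was smaller for long genes (Spearman's rho = -0.33 over 377 genes, across genes, which are not independent replicates). With the autosomal trend removed rho was -0.25. Over the 223 genes at or above the upper quartile signal of chicken probe sets, 6.79, it was -0.33. The permutation p was 1e-04 for each, the smallest that 10000 draws can give. The shortest 76 Z genes had a median of 0.64 and the longest 76 a median of 0.09.

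The arrays were also split into every pair of groups of 3. With 10 splits a share under 0.05 cannot be had. Every other split mixes the sexes in both groups, so part of the sex difference stays in its contrast and part adds to its spread. The other splits therefore do not show what arrays without a sex difference would give. The real split gave 209 probe sets and the highest other 2, 11 autosomal probe sets and 2, 7 lists and 5, and a Z shift of 0.43 and 0.21, so that 1 split, the real one, was as large in each. On autosomal members the real split gave 5 lists and another gave 6, so 2 splits were as large. For the MHM list -log10 p was 4.26 for the real split and 4.69 for the highest other, so 2 splits were as large. That other split grouped female pools 1 and 3 with male pool 1, and its mean difference was -0.13 against -0.30. For the Z genes with a W copy the values were 2.11 and 1.74, with 1 split, the real one, as large.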
